A study of Mus musculus with 13 samples.

How the data were processed

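Polyadenylated RNA was sequenced from 5 PDGFB tumors, 5 RAS tumors and 3 normal brain samples of mice. Per the labels, RNA was isolated with Trizol and libraries were made with a TruSeq RNA kit, which leaves open whether the strand of the RNA was marked. The submitters' processing notes name fastp 0.22.0, STAR 2.7.9a and the genome build GRCm38; neither the gene annotation nor the strand setting of the count is stated. The deposited values were raw counts, whole reads for each of 55416 Ensembl genes and 13 libraries, with no normalization by the authors, after the summary lines of the aligner for unmapped, multimapping, unassigned and ambiguous reads.

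Groups and replicate numbers came from the titles of the tumor samples and from the tissue label of the normal samples. A normal title begins with other letters than the remaining ones, and all were grouped by their tissue label. A label that describes normal tissue trimmed from tumor tissue does not say whether it is the source of the normal samples. Symbols, positions and strands were matched by Ensembl identifier to GENCODE M21 (GRCm38), which held 52135 of the genes; 3281 were not in it and none of these is named. For each gene the exons were compared with exons of genes on the other strand, which put it opposite an exon, opposite an intron or opposite no gene.

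Libraries held 13952738 to 15607754 reads. Unmapped reads made up 2.05% to 4.89%, multimapping reads 5.40% to 7.35%, reads in no gene 84.5% to 87.3% and ambiguous reads 0.0516% to 0.0805%, which left 529162 to 643055 counts for genes. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

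Genes were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter filterByExpr (minimum count 10, minimum total 15) kept 7722 genes, TMM factors set the scale, and a quasi-likelihood model with 1 coefficient per group over all 13 libraries gave the 3 comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; all tests were two-sided. CPM used the total counted for genes. A fold against a group with no read is a lower bound from 3 reads over that group; with 1 to 3 reads in a group, the ratio of counts is given with its 95% counting interval. The fitted log2 fold change of such a gene depends on the prior count and is no bound.

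Before the data were examined, 32 gene lists with 504 entries, all matched, were fixed. The lists were mature oligodendrocyte, oligodendrocyte precursor, astrocyte, reactive astrocyte, neural progenitor, neuron, macrophage and microglia, homeostatic microglia, monocyte-derived macrophage, fibroblast and meninges, extracellular matrix, cell cycle, mesenchymal glioma, classical glioma, hypoxia and glycolysis, MAPK output, p53 targets, immediate early, MHC class I presentation, MHC class II presentation, interferon response, cholesterol synthesis, oxidative phosphorylation and ribosomal proteins (these 24 had at least 3 members tested), and neutrophil, T and NK cell, B cell, endothelial, pericyte and smooth muscle, choroid plexus and ependyma, red blood cell and cytokines and chemokines (these 8 had fewer). Some markers are shared by cell types: macrophage and MHC genes are made by several immune cells, and Cnp and other glial genes by the tissue the tumors arose in. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over the 72 tests of 24 lists in 3 comparisons. Camera with an estimated correlation and the rotation test fry were run beside it. Summed CPM of the 8 other lists were compared by exact permutation tests.

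Named genes were chosen by a rule set before the data were examined: the 4 genes of the design, then per comparison up to 10 higher and 10 lower genes with the largest absolute log2 fold change among those called, with no overlap of CPM between groups, a mean of at least 10 CPM in the higher group and a symbol that is not a predicted gene or an immune receptor segment, and per list 1 to 4 members, those called with the largest change or else the most abundant. How many members were named was settled after values were seen, at 2 for called and 1 for other lists, and genes without a symbol were left out then. Results of some genes are not reported here, though counts of genes, list members and outlying values include them.

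Alternatives set beforehand were median-of-ratios factors, library totals, no filter, a looser filter (1 CPM in 5 libraries), DESeq2 1.42.0, limma-voom, fits of the 2 compared groups alone, an adjusted p under 0.01, a minimum of 2-fold, leaving out each library, and between tumors the replicate number as a block and the neuron or macrophage list as a covariate. Added after seeing the data were a fit of genes with none on the opposite strand, a count in which reads were moved to the opposite gene, and the attention given to RAS tumor 2. In the moved count, a gene whose exons overlap exons of exactly 1 protein-coding gene on the other strand gave its reads to that gene (70.5% of reads), and genes with several were dropped (9.22%).

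The test was checked on simulated counts at the depth and spread of these libraries. Of genes changed 4-fold, 79.6%, 82.1% and 87.0% were called for PDGFB against normal, RAS against normal and PDGFB against RAS, and of those changed 2-fold 17.8%, 14.8% and 41.5%. False calls made up 5.26%, 2.15% and 4.80%. All columns of the table were used. No sample was left out.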

Results

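Gene expression was measured by sequencing polyadenylated RNA from 13 pieces of mouse tissue. Glioblastomas had been induced in the motor cortex by a lentivirus in mice that express Cre recombinase from the oligodendrocyte gene Cnp. The PDGFB tumors (n = 5) carried a virus with PDGFB, a growth factor of the platelet-derived family, and the RAS tumors (n = 5) one with an oncogenic HRas; both viruses also carried a short hairpin RNA against p53. Tumor tissue marked by GFP was taken when the mice reached their clinical endpoint, from 5 mice per tumor group. Normal brain tissue from mice labelled wild type formed the third group (n = 3). Its tissue label names no brain region, so a difference from the tumors can also be one of region. Its titles mark both sexes but no animal count, so samples may share animals. P-values pool spread over 13 libraries.

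Each library held 13952738 to 15607754 reads, of which 529162 to 643055 (median 608897) were counted for a gene. Reads counted for genes averaged 613865 ± 13669 (SD, n = 5) in PDGFB tumors, 616145 ± 20699.9 (SD, n = 5) in RAS tumors and 573822 ± 39697 (SD, n = 3) in normal brain. They made up 4.24% to 4.75% of the uniquely mapped reads, and 95.2% to 95.7% fell in no gene. Most counted reads, 84.0%, stood under the 16.1% of genes whose exons overlap an exon of another gene on the opposite strand. Those genes held 187 reads per kb of exon, and genes with none on the opposite strand 12.8. The most abundant entry, Gm20721, lies opposite Gnas, LTO1 lies opposite the cyclin gene Ccnd1, and mt-Nd6, the sole mitochondrial messenger of its strand, exceeded the other 12 together by 1.80 to 4.19 times. A gene name or list member thus means reads deposited under it, perhaps another gene's. “Opposite” and a name give the gene whose exons overlap it on the other strand.

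The genes named in the design were examined first in every library. Trp53, the target of the hairpin (chromosome 11, 69580359 to 69591873, GRCm38), had 0 to 5 reads per library and was too low to test. A knockdown could therefore not be judged from these counts. The low count need not mean shallow sequencing or low expression, since 95.2% to 95.7% of uniquely mapped reads fell in no gene. Pdgfb (opposite an intron) had 4 to 21 reads in the 5 PDGFB tumors, 1 to 4 in the 5 RAS tumors and 3 to 6 in the 3 normal brains, and was not tested either. Hras averaged 16.1 ± 7.62 CPM (read counts scaled to a common library total) in PDGFB tumors, 25.2 ± 10.3 in RAS tumors and 36.1 ± 5.84 in normal brain. It was lower in PDGFB tumors than in normal brain (log2 fold change −1.15 ± 0.40 SE, adjusted p = 0.0272). That call ended without PDGFB tumor 2 or 3 or any normal brain, under library totals and with no or a looser low-count filter (adjusted p 0.0561 to 0.124). RAS tumors did not differ from normal brain (log2 fold change −0.50, adjusted p = 0.286) or from PDGFB tumors (−0.64, adjusted p = 0.187) past the threshold. Cnp (opposite Dnajc7), which drives the Cre, had 309 to 453 reads. Its log2 fold changes, in PDGFB and RAS tumors against normal and between tumors, were −0.19, −0.29 and 0.10 (adjusted p 0.352, 0.128 and 0.604). Whether Cnp reads are Dnajc7's, or a viral transcript adds to Pdgfb or Hras, cannot be read from these counts.

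The 3 groups stood apart in a principal component analysis of the 7722 genes tested. The first component (56.4% of the variance) ran from RAS tumors to normal brain, and the second (19.4%) set the PDGFB tumors apart from both. RAS tumor 2 stood at −11.2 on the first component and the other 4 RAS tumors at −53.3 to −71.4. No replicate pair had counts within sampling noise of each other (lowest chi-square per degree of freedom 1.90), so all 13 libraries were kept as separate samples.

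**Figure D1:**
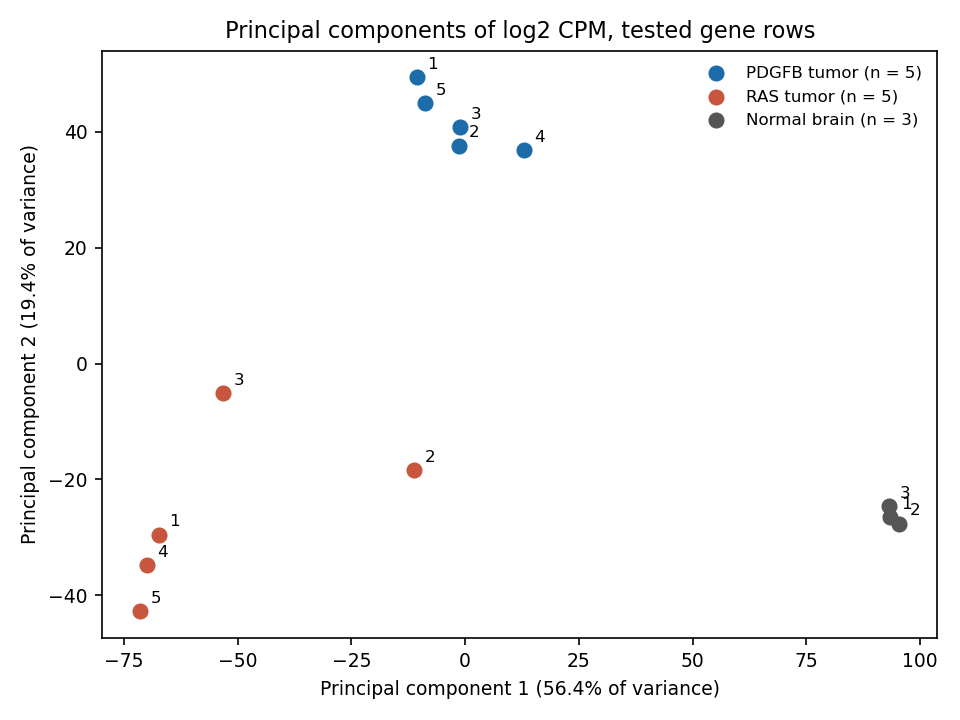
Principal components of log2 CPM over the genes tested, in component units, 1 point per library with its replicate number (5 PDGFB tumors, 5 RAS tumors, 3 normal brains). The normal brains sit at 93.2 to 95.5 on the first axis, the PDGFB tumors at −10.7 to 12.98, and RAS tumor 2 at −11.2.

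What distinguishes a PDGFB tumor from normal brain was asked first. Many genes of cell division, oligodendrocyte precursors and neural progenitors were higher in the 5 PDGFB tumors than in the 3 normal brains, and many of neurons and mature oligodendrocytes lower. These lists passed camera's test, and none did with the correlation between members estimated (adjusted p = 0.121 to 0.461 over the called lists). The progenitor filament gene Nes averaged 107 ± 16.9 CPM (SD, n = 5) against 0 in normal brain, and the myelin gene Mbp 45.2 ± 19.0 CPM against 601 ± 110.0 (SD, n = 3). Of 7722 genes tested, 1558 were higher and 1940 lower at an adjusted p under 0.05. With library totals in place of composition factors the counts were 2045 and 1556, as the median gene shifted by 0.23 on the log2 scale, so the balance between higher and lower rests on the scaling. CPM of the groups did not overlap for 3909 genes, 50.6% of those tested (chance 3.57%).

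The 10 highest named genes had no read in normal brain, so their folds are lower bounds set by 3 reads over the group. Nes (ENSMUSG00000004891, chromosome 3, 87971078 to 87980451) was at least 53.7-fold higher, adjusted p = 1.64e-07, and Cdsn, a desmosomal protein of skin (chromosome 17, 35552128 to 35557180), was at least 48.4-fold higher, adjusted p = 3.83e-06. The spindle assembly factor Tpx2 (chromosome 2, 152847964 to 152895321) was at least 18.7-fold higher, adjusted p = 8.62e-05, and the mitotic kinase Cdk1 was at least 11.6-fold higher, adjusted p = 1.74e-04. Pnlip, a pancreatic lipase, the homeobox gene Hlx and the tumor suppressor locus Cdkn2a were at least 17.0-, 15.9- and 12.1-fold higher. Hmga2 (opposite 1700006J14Rik), an embryonic chromatin protein, the kinetochore gene Cenpf and the endothelial receptor Cd93 were at least 11.9-, 10.2- and 10.2-fold higher (adjusted p at most 5.01e-04 for these 6 genes). Among the 10 lowest, Parpbp (opposite Pmch), which shares its place with the melanin-concentrating hormone gene, was 276-fold lower, log2 fold change −8.11 ± 0.52 SE, adjusted p = 2.19e-08 (chromosome 10, 88091432 to 88146941). Its direction turned when reads were moved to the opposite gene (log2 fold change 3.77). Myocos (opposite Myoc, the myocilin gene) was lower with a count ratio of 458, 95% interval 81.3 to 18158, adjusted p = 8.75e-08. Ttr, the thyroxine carrier made by the choroid plexus, was lower with a count ratio of 155, 95% interval 42.3 to 1295, adjusted p = 4.37e-06. For genes of a particular part of the brain, such as Ttr and Pmch, a difference of region cannot be told apart from a change in the tumors. The synaptic vesicle gene Rph3a was 41.4-fold lower, log2 fold change −5.37 ± 0.66 SE, adjusted p = 9.48e-06, and the calcium channel subunit gene Cacng3 was lower with a count ratio of 63.0, 95% interval 10.5 to 2569.5, adjusted p = 4.82e-05. The others were Myh7 (opposite Gm31251), Tmem130, Scn9a (opposite Gm13629), Krt12 (opposite A830036E02Rik) and Arc, a gene induced by neuronal activity, with adjusted p at most 4.74e-04.

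Cell cycle, oligodendrocyte precursor, neural progenitor and MAPK output lists rose. Each list is given with the members that passed (in parentheses, higher and lower when adjusted over the list alone, here and in the later comparisons), the median log2 fold change of all tested, camera's adjusted p, and the range of adjusted p over the alternatives run. In the cell cycle list 13 of 15 rose, 0 fell and 2 did not pass (13 and 0; median 4.50 (3.53 with members at their bound), adjusted p = 2.32e-06, and adjusted p = 0.213 with an estimated correlation (alternatives 2.95e-09 to 0.213)), Tpx2 and Cdk1 among them. In the oligodendrocyte precursor list 14 of 18 rose, 0 fell and 4 did not pass (15 and 0), with median 2.55, adjusted p = 7.44e-07, and adjusted p = 0.222 with an estimated correlation (alternatives 3.09e-08 to 0.222). Its proteoglycan gene Cspg4 was higher with a count ratio of 47.6, 95% interval 8.36 to 1900, adjusted p = 5.14e-05. Pcdh15, a protocadherin, was higher with a count ratio of 18.1, 95% interval 4.84 to 152, adjusted p = 4.03e-04. Of the neural progenitor list 6 of 11 rose, 2 fell and 3 did not pass (6 and 2), with median 1.69 (1.69 with members at their bound), adjusted p = 0.0111, and adjusted p = 0.121 with an estimated correlation (alternatives 1.11e-05 to 0.121). Fabp7, a fatty acid binding protein of radial glia, was 28.5-fold higher, log2 fold change 4.83 ± 0.76 SE, adjusted p = 8.16e-05. Of the MAPK output list, genes induced by signaling through the kinase Erk, 6 of 17 rose, 0 fell and 11 did not pass (6 and 0), with median 1.16 (0.82 with members at their bound), adjusted p = 0.0111, and adjusted p = 0.188 with an estimated correlation (alternatives 1.51e-04 to 0.188). Ccnd1 (opposite LTO1) was 6.01-fold higher, log2 fold change 2.59 ± 0.20 SE, adjusted p = 8.75e-08, and Phlda1 (opposite Gm28592) 6.62-fold higher, adjusted p = 1.42e-04. Over the genes with none on the opposite strand the MAPK list no longer passed, though its median stayed (median 1.11 against 1.16, adjusted p = 0.0771).

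Reactive astrocyte, mesenchymal glioma, matrix, ribosomal protein and interferon lists also rose. In the reactive astrocyte list 2 of 5 rose, 0 fell and 3 did not pass (2 and 0), with median 1.03, adjusted p = 0.0202, and adjusted p = 0.143 with an estimated correlation (alternatives 1.17e-06 to 0.143). The filament gene Vim was 21.7-fold higher, log2 fold change 4.44 ± 0.37 SE, adjusted p = 1.84e-07, and the protease inhibitor gene Serpina3n higher with a count ratio of 100.03, 95% interval 17.8 to 3969.6, adjusted p = 1.38e-05. In the mesenchymal glioma list 9 of 19 rose, 1 fell and 9 did not pass (10 and 1; median 2.30 (1.66 with members at their bound), adjusted p = 0.00456, and adjusted p = 0.351 with an estimated correlation (alternatives 6.03e-04 to 0.351)). Cd44, the hyaluronan receptor, was at least 5.40-fold higher, adjusted p = 4.79e-04, and the actin-binding gene Tagln2 higher with a count ratio of 40.8, 95% interval 13.8 to 199, adjusted p = 7.31e-07. In the extracellular matrix list 9 of 16 rose, 1 fell and 6 did not pass (11 and 1), with median 2.59 (1.30 with members at their bound), adjusted p = 0.00395, and adjusted p = 0.337 with an estimated correlation (alternatives 6.03e-04 to 0.337); over genes with none on the opposite strand it did not pass (median 1.37 against 2.59, adjusted p = 0.229). Tnc (opposite 8030451A03Rik), a matrix glycoprotein, was 17.3-fold higher, log2 fold change 4.12 ± 0.52 SE, adjusted p = 1.22e-05. Postn was at least 2.54-fold higher, adjusted p = 0.0373, with overlapping libraries, a call lost in limma-voom and without PDGFB tumor 1 or 5 or any normal brain (adjusted p without a library 0.0516 to 0.0818; 0.00986 to 0.137 over its alternatives). Of the ribosomal protein list 12 of 17 rose, 0 fell and 5 did not pass (13 and 0), with median 1.24, adjusted p = 8.31e-04, and adjusted p = 0.461 with an estimated correlation (alternatives 1.90e-04 to 0.461). Rplp0 was 5.82-fold higher, log2 fold change 2.54 ± 0.35 SE, adjusted p = 2.67e-05 and Rps9 4.01-fold higher, adjusted p = 2.55e-04. Of the interferon response list 3 of 4 rose, 0 fell and 1 did not pass (3 and 0), with median 2.49, adjusted p = 0.0380, and adjusted p = 0.314 with an estimated correlation (alternatives 4.12e-04 to 0.314). The antiviral gene Ifit2 was higher with a count ratio of 38.1, 95% interval 6.65 to 1524, adjusted p = 4.24e-04, and the GTPase gene Irgm1 7.79-fold higher, adjusted p = 0.00396. This call ended, though the median stayed positive, under library totals (median 2.72, adjusted p = 0.0542), without RAS tumor 5 (2.58, adjusted p = 0.0512) and without normal brain 1 (1.93, adjusted p = 0.0505).

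Neuron and myelin lists fell. Of the neuron list 0 of 19 rose, 18 fell and 1 did not pass (0 and 18), with median −3.30, adjusted p = 1.09e-08, and adjusted p = 0.222 with an estimated correlation (alternatives 2.62e-15 to 0.222). Nefm (opposite Nefl), both neurofilament genes, was 17.8-fold lower, log2 fold change −4.15 ± 0.29 SE, adjusted p = 4.16e-08, and the synaptic kinase gene Camk2a 17.1-fold lower, log2 fold change −4.09 ± 0.69 SE, adjusted p = 1.58e-04. Of the mature oligodendrocyte list 0 of 7 rose, 4 fell and 3 did not pass (0 and 4), with median −3.38, adjusted p = 0.0111, and adjusted p = 0.337 with an estimated correlation (alternatives 5.92e-04 to 0.337). Mbp (chromosome 18, 82475146 to 82585637) was 13.2-fold lower, log2 fold change −3.73 ± 0.40 SE, adjusted p = 3.15e-06. Mag, a glycoprotein of myelin, was 17.9-fold lower, adjusted p = 1.37e-04.

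The other 13 lists tested did not pass in this comparison. The astrocyte list had 0 of 12 higher and 5 lower (0 and 5), median −1.21, adjusted p = 0.139. The glycolytic gene Aldoc was 7.99-fold lower, log2 fold change −3.00 ± 0.56 SE, adjusted p = 3.55e-04. The list passed without normal brain 2 (median −1.72 against −1.21, adjusted p = 0.0444, 0.00692 to 0.490 over its alternatives). MHC class I presentation had 4 of 7 higher and 0 lower (5 and 0), median 2.24, adjusted p = 0.0671. H2-Q4 (opposite Gm11131) was higher with a count ratio of 15.2, 95% interval 2.55 to 621, adjusted p = 0.0229, lost without normal brain 1 or 3 and in limma-voom (adjusted p = 0.0760, 0.0771 and 0.0915). The list passed without normal brain 1 (median 2.49 against 2.24, adjusted p = 0.0490, 0.00903 to 0.433 over its alternatives) and without normal brain 2 (median 2.75, adjusted p = 0.0165). MHC class II presentation had 1 of 5 higher and 0 lower (0 and 0), median 3.97 (0.67 with members at their bound), adjusted p = 0.591. H2-DMa (opposite Brd2) had a log2 fold change of −0.12 (adjusted p = 0.687). Macrophage and microglia genes had 3 of 10 higher and 1 lower (4 and 1), median 1.06, adjusted p = 0.163. Lyz2, a lysozyme of myeloid cells, was 4.89-fold higher, log2 fold change 2.29 ± 0.60 SE, adjusted p = 0.00473. Homeostatic microglia genes had 1 of 4 higher and 1 lower (1 and 2), median −0.26, adjusted p = 0.896. Selplg was 3.35-fold lower, log2 fold change −1.74 ± 0.56 SE, adjusted p = 0.0165, lost without normal brain 1 or 3 (adjusted p = 0.0905 and 0.0632). Monocyte-derived macrophage genes had 4 of 8 higher and 0 lower (4 and 0), median 2.43 (1.73 with members at their bound), adjusted p = 0.113. Gpnmb was at least 3.49-fold higher, adjusted p = 0.0115. The list passed in genes with none on the opposite strand (median 3.49 against 2.43, adjusted p = 0.0308, 0.00612 to 0.389 over its alternatives). The fibroblast list had 0 of 3 higher and 0 lower (0 and 0), median 0.50, adjusted p = 0.745, with the collagen gene Col1a2 at a log2 fold change of 0.50. For classical glioma, 1 of 4 higher and 1 lower (1 and 1), median 0.35, adjusted p = 0.955, the mean was 0.23 and the test pointed down. Gas1 (opposite Gm48488) was 3.84-fold higher, adjusted p = 0.0392, lost in limma-voom and without PDGFB tumor 1, 4 or 5 or normal brain 2 or 3 (adjusted p up to 0.121). Hypoxia and glycolysis had 2 of 11 higher and 1 lower (2 and 1), median 0.46, adjusted p = 0.416, and the peptide hormone gene Adm (opposite an intron) was higher with a count ratio of 39.1, 95% interval 6.82 to 1561, adjusted p = 1.12e-04. Among p53 targets, 3 of 9 higher and 2 lower (3 and 2), median 0.0067, adjusted p = 0.581. Rps27l was 6.89-fold higher, adjusted p = 5.65e-04. Immediate early genes had 0 of 5 higher and 3 lower (0 and 3), median −1.26, adjusted p = 0.244. Arc was lower with a count ratio of 31.5, 95% interval 10.1 to 158, adjusted p = 4.74e-04. Cholesterol synthesis had 1 of 9 higher and 1 lower (1 and 1), median −0.010, adjusted p = 0.827, with a mean of 0.045 and a test that pointed up. Its enzyme gene Sqle was 2.32-fold higher, adjusted p = 2.64e-04. Oxidative phosphorylation had 0 of 15 higher and 4 lower (0 and 2), median −0.59, adjusted p = 0.189. Sdha, of the succinate dehydrogenase, was 2.36-fold lower, adjusted p = 0.00373.

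The RAS tumors were compared with normal brain in the same way. Most genes of the extracellular matrix, mesenchymal glioma, macrophages, MHC class I presentation and the cell cycle were higher in the 5 RAS tumors than in the 3 normal brains, and most of neurons and myelin lower. The list calls behind this did not hold with an estimated correlation (adjusted p = 0.121 to 0.351). Thbs2, a matrix thrombospondin, averaged 167 ± 121 CPM (SD, n = 5) against 0 in normal brain, and the lysozyme gene Lyz2 188 ± 28.1 against 3.82 ± 4.86 (SD, n = 3). Of 7722 genes, 2081 were higher and 2259 lower. Library totals gave 2225 and 2095, with the median gene shifted by 0.093, and the counts without RAS tumor 2 were 2311 and 2159. CPM did not overlap for 4049 genes, 52.4% of those tested (chance 3.57%).

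All 10 of the highest named genes lacked reads in normal brain. Nes was at least 110.0-fold higher, adjusted p = 1.87e-08. Hmga2 (opposite 1700006J14Rik) was at least 102-fold higher, adjusted p = 7.69e-08. Timp1 (opposite an intron), an inhibitor of matrix proteases (chromosome X, 20870166 to 20874735), was at least 85.7-fold higher, adjusted p = 1.44e-06. Thbs2 (chromosome 17, 14665500 to 14694235) was at least 84.1-fold higher, adjusted p = 8.23e-06, and the cytokine gene Il27 (opposite Apobr) at least 51.0-fold higher, adjusted p = 1.11e-05. The matrix protein gene Fbln2, the annexin gene Anxa1 (opposite an intron), the calcium-binding gene S100a11, the receptor gene Cd44 and the membrane repair gene Myof were at least 48.2-, 44.0-, 42.2-, 37.9- and 36.0-fold higher (adjusted p at most 1.84e-05). Among the lowest, Ttr had no read in RAS tumors and was at least 94.2-fold lower, adjusted p = 1.60e-06 (chromosome 18, 20665280 to 20674321). As for the PDGFB tumors, this cannot be told apart from a difference of region. Parpbp (opposite Pmch) was 205-fold lower, log2 fold change −7.68 ± 0.51 SE, adjusted p = 1.11e-08, and turned with moved reads (log2 fold change 2.95). Myocos (opposite Myoc) was 74.2-fold lower, log2 fold change −6.21 ± 0.52 SE, adjusted p = 1.24e-07. Epyc (opposite Gm10754) was lower with a count ratio of 242, 95% interval 42.7 to 9652, adjusted p = 2.70e-06. The neuronal transcription factor gene Neurod2 was lower with a count ratio of 71.9, 95% interval 23.99 to 354, adjusted p = 6.37e-06, and the sodium channel subunit gene Scn3b lower with a count ratio of 85.9, 95% interval 14.7 to 3468, adjusted p = 1.79e-05. Hpca (opposite Tmem54), a neuronal calcium sensor, was 52.6-fold lower, log2 fold change −5.72 ± 0.60 SE, adjusted p = 1.08e-06. Strc (opposite Ckmt1), Vmn2r57 (opposite Gm17102) and Tmem130 completed the 10, with adjusted p at most 4.19e-06.

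Matrix and mesenchymal lists rose. Of the mesenchymal glioma list 18 of 19 rose, 1 fell and 0 did not pass (18 and 1), with median 5.85 (5.24 with members at their bound), adjusted p = 1.95e-10, and adjusted p = 0.121 with an estimated correlation (alternatives 3.29e-14 to 0.121). Timp1 and Anxa1 were its largest changes. Of the extracellular matrix list 16 of 16 rose, 0 fell and 0 did not pass (16 and 0), with median 4.33 (4.13 with members at their bound), adjusted p = 5.81e-09, and adjusted p = 0.121 with an estimated correlation (alternatives 1.36e-09 to 0.121). The collagen genes Col6a1 and Col5a2 were at least 29.2-fold higher, adjusted p = 1.16e-04, and at least 22.5-fold higher, adjusted p = 1.21e-04, respectively. Macrophage, monocyte-derived macrophage and MHC class I lists rose as well. Of the macrophage and microglia list 9 of 10 rose, 0 fell and 1 did not pass (9 and 0), with median 2.84, adjusted p = 2.14e-04, and adjusted p = 0.238 with an estimated correlation (alternatives 3.44e-05 to 0.238). Lyz2 was 45.2-fold higher, log2 fold change 5.50 ± 0.53 SE, adjusted p = 4.68e-07, and the protease gene Ctss 10.8-fold higher, log2 fold change 3.43 ± 0.36 SE, adjusted p = 1.13e-06. Of the monocyte-derived macrophage list 7 of 8 rose, 0 fell and 1 did not pass (7 and 0), with median 5.09 (3.95 with members at their bound), adjusted p = 9.41e-04, and adjusted p = 0.135 with an estimated correlation (alternatives 2.14e-05 to 0.135). Spp1, osteopontin, was 172-fold higher, log2 fold change 7.42 ± 0.75 SE, adjusted p = 7.53e-07, and the lectin gene Lgals3 at least 30.7-fold higher, adjusted p = 2.21e-05. Of the MHC class I presentation list 6 of 7 rose, 0 fell and 1 did not pass (6 and 0), with median 4.37, adjusted p = 0.00173, and adjusted p = 0.241 with an estimated correlation (alternatives 1.55e-04 to 0.241). H2-D1 was 33.0-fold higher, log2 fold change 5.04 ± 0.74 SE, adjusted p = 2.66e-05, and H2-Q4 (opposite Gm11131) higher with a count ratio of 35.1, 95% interval 6.09 to 1406, adjusted p = 0.00130, with overlapping libraries.

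The cell cycle, MAPK output, reactive astrocyte and ribosomal protein lists also rose, and the neuron and mature oligodendrocyte lists fell. Of the cell cycle list 13 of 15 rose, 0 fell and 2 did not pass (14 and 0), with median 3.82 (2.53 with members at their bound), adjusted p = 0.00197, and adjusted p = 0.337 with an estimated correlation (alternatives 2.08e-04 to 0.337). Tpx2 was at least 18.9-fold higher, adjusted p = 5.05e-05, and Cdk1 at least 8.21-fold higher, adjusted p = 3.26e-04. Of the MAPK output list 12 of 17 rose, 0 fell and 5 did not pass (13 and 0), with median 1.51 (1.51 with members at their bound), adjusted p = 1.93e-04, and adjusted p = 0.121 with an estimated correlation (alternatives 5.19e-06 to 0.121). The growth factor genes Areg and Ereg (opposite Gm19610) were at least 21.3-fold higher, adjusted p = 2.38e-04, and at least 27.4-fold higher, adjusted p = 1.60e-05. Of the reactive astrocyte list 2 of 5 rose, 0 fell and 3 did not pass (2 and 0), with median 1.52, adjusted p = 0.0111, and adjusted p = 0.121 with an estimated correlation (alternatives 2.27e-07 to 0.121); Vim was 54.0-fold higher, log2 fold change 5.75 ± 0.38 SE, adjusted p = 1.11e-08, and Serpina3n higher with a count ratio of 166, 95% interval 29.6 to 6578, adjusted p = 1.79e-06. Of the ribosomal protein list 17 of 17 rose, 0 fell and 0 did not pass (17 and 0), with median 2.10, adjusted p = 3.95e-06, and adjusted p = 0.351 with an estimated correlation (alternatives 8.74e-07 to 0.351); Rplp0 was 10.8-fold higher, log2 fold change 3.43 ± 0.36 SE, adjusted p = 9.89e-07. Of the neuron list 0 of 19 rose, 16 fell and 3 did not pass (0 and 17), with median −3.56, adjusted p = 2.89e-05, and adjusted p = 0.337 with an estimated correlation (alternatives 5.11e-10 to 0.337). Snap25, of the synaptic fusion machinery, was 24.6-fold lower, log2 fold change −4.62 ± 0.77 SE, adjusted p = 8.04e-05, and the nuclear marker gene Rbfox3 20.7-fold lower, log2 fold change −4.37 ± 0.69 SE, adjusted p = 5.24e-05. In the mature oligodendrocyte list 0 of 7 rose, 6 fell and 1 did not pass (0 and 6), with median −2.94, adjusted p = 0.00658, and adjusted p = 0.325 with an estimated correlation (alternatives 6.73e-05 to 0.325); Mbp was 13.7-fold lower, adjusted p = 1.34e-06, and Mobp 15.5-fold lower, adjusted p = 4.98e-05.

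In RAS tumors against normal brain, 13 lists did not pass. The oligodendrocyte precursor list had 5 of 18 higher and 2 lower (4 and 2), median 0.23, adjusted p = 0.581; Cspg4 was higher with a count ratio of 13.1, 95% interval 2.14 to 538, adjusted p = 0.00520. Neural progenitor genes had 4 of 11 higher and 3 lower (5 and 3), median 0.60 (0.60 with members at their bound), adjusted p = 0.202, Nes being the largest change. Astrocyte genes had 1 of 12 higher and 5 lower (1 and 5), median −1.27, adjusted p = 0.173. Slc1a2 (opposite Gm13872), a glutamate transporter, was 10.2-fold lower, log2 fold change −3.36 ± 0.54 SE, adjusted p = 5.76e-05. For homeostatic microglia there were 1 of 4 higher and 0 lower (1 and 0), median 0.49, adjusted p = 0.450. Cx3cr1 (opposite Gm33858) had a log2 fold change of 0.32 (adjusted p = 0.391). The fibroblast list had 3 of 3 higher and 0 lower (3 and 0), median 3.71, adjusted p = 0.113. Col1a2 was 21.3-fold higher, log2 fold change 4.41 ± 0.80 SE, adjusted p = 1.69e-04. MHC class II presentation had 3 of 5 higher and 2 lower (3 and 2), median 6.87 (3.65 with members at their bound), adjusted p = 0.581. Cd74, the class II invariant chain, was at least 22.9-fold higher, adjusted p = 1.81e-04. Interferon response genes had 4 of 4 higher and 0 lower (4 and 0), median 2.18, adjusted p = 0.130. Ifit2 was higher with a count ratio of 31.9, 95% interval 5.52 to 1282, adjusted p = 5.25e-04. Classical glioma genes had 1 of 4 higher and 0 lower (1 and 0), median −0.0053, adjusted p = 0.827, with a mean of 0.21 and a test that pointed up. Pdgfa (opposite 6330403L08Rik) had a log2 fold change of −0.099. Hypoxia and glycolysis genes had 6 of 11 higher and 0 lower (7 and 0), median 1.29, adjusted p = 0.109. Adm (opposite an intron) was higher with a count ratio of 13.6, 95% interval 2.24 to 558, adjusted p = 0.00457. The p53 targets had 5 of 9 higher and 2 lower (5 and 2), median 1.75, adjusted p = 0.436. Rps27l was 7.82-fold higher, adjusted p = 1.87e-04. Immediate early genes had 0 of 5 higher and 3 lower (0 and 3), median −0.97, adjusted p = 0.425. Arc was 8.23-fold lower, adjusted p = 0.00267. Cholesterol synthesis genes had 3 of 9 higher and 1 lower (3 and 1), median 0.63, adjusted p = 0.549. Dhcr7 was 3.84-fold higher, adjusted p = 0.0164, lost without normal brain 3 (adjusted p = 0.0563). Oxidative phosphorylation genes had 0 of 15 higher and 3 lower (0 and 0), median −0.20, adjusted p = 0.632. Ndufs1 (opposite Ino80dos) was 1.90-fold lower, adjusted p = 0.0151, lost with no low-count filter and without RAS tumor 1 or normal brain 1 or 3 (adjusted p up to 0.0829) and reversed when reads were moved to the opposite gene (log2 fold change 2.80).

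Both tumor groups were set against the same 3 normal brains, so a chance high or low normal library moves both comparisons alike. Of the genes tested, 1125 were higher in both tumor groups, where independent lists of these sizes would share 419.9, and 1623 lower, against 568. Groups simulated as unchanged gave 0 calls in edgeR, so the overlap that shared normals add to real changes was not measured. Across genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.818, against 0.638 in the simulated groups, and their covariance was 2.72 against 0.109. The 3 normals were too few to divide between the comparisons. In 38 genes the tumor groups moved apart from normal brain in opposite directions, independent lists giving 979.

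The last comparison asked how the oncogene in the virus was reflected in the tumor. Oligodendrocyte precursor genes were higher in the 5 PDGFB tumors than in the 5 RAS tumors, while most matrix, mesenchymal, macrophage, MHC class I and ribosomal protein genes were lower. No list call held with an estimated correlation (adjusted p = 0.121 to 0.491), and those of MHC class I and ribosomal protein genes ended with the macrophage list as a covariate. Pcdh15 averaged 23.8 ± 9.39 CPM in PDGFB tumors (SD, n = 5), 0.698 ± 0.958 in RAS tumors (SD, n = 5) and 1.38 ± 1.20 in normal brain (SD, n = 3). Lyz2 averaged 20.1 ± 8.60 CPM in PDGFB tumors against 188 ± 28.1 in RAS tumors. Of 7722 genes, 1130 were higher and 1346 lower in PDGFB tumors, and CPM did not overlap for 1522, 19.7% of those tested (chance 0.794%).

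Library totals gave 1445 higher and 1075 lower genes, with the median gene shifted by 0.14. Leaving out RAS tumor 2, the RAS tumor nearest to normal brain, gave 1541 and 1502. With the macrophage and microglia list as a covariate, which itself differed between the tumor groups, 4 genes were higher and 57 lower of 5688 above the filter over the 10 tumors. Of the 47 named genes called between tumors, 8 kept their call with it (Angptl2, Nid1, Erap1, Thbs2, Anxa1, Ereg, Oaf and Fam69c), 22 lost it and 17 fell below the filter. Of those lost, 14 kept at least 0.5 of their log2 fold change (Spp1 −4.12 against −4.36, adjusted p = 0.0568), 6 kept less and 2 reversed. The median SE rose from 0.53 to 1.12, so a lost call there does not show that macrophage content accounts for a difference. With the neuron list as a covariate the counts were 926 and 982.

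Among the 10 highest named genes, Pcdh15 (chromosome 10, 73099342 to 74649737) was higher with a count ratio of 34.6, 95% interval 9.24 to 291, adjusted p = 4.26e-05. Fendrr, a long noncoding RNA (opposite an intron), was 14.1-fold higher, log2 fold change 3.82 ± 0.42 SE, adjusted p = 4.33e-06, and Fam69c (opposite D030046N08Rik) 14.0-fold higher, log2 fold change 3.80 ± 0.46 SE, adjusted p = 1.18e-05. The zinc finger gene Sall3 was 15.9-fold higher, log2 fold change 3.99 ± 0.71 SE, adjusted p = 4.03e-04. Dcx, of migrating neuroblasts, was higher with a count ratio of 16.1, 95% interval 5.21 to 80.4, adjusted p = 0.00149. Napsa (opposite Gm15396) was higher with a count ratio of 62.8, 95% interval 10.9 to 2514, adjusted p = 1.84e-05, and its direction turned when reads were moved to the opposite gene (log2 fold change −0.47). Lmo3 (opposite an intron), Rimklb, C1ql2 and Pex11a completed this group (adjusted p at most 7.09e-04). Of the 10 lowest, Grem1, an antagonist of bone morphogenetic proteins (chromosome 2, 113746164 to 113758646), was at least 70.7-fold lower, adjusted p = 5.35e-05. Oaf was at least 47.6-fold lower, adjusted p = 4.95e-06. Slco2a1 (opposite n-R5s89), a prostaglandin transporter, Dmrt1i (opposite Baiap2l1) and the semaphorin gene Sema3b were at least 33.7-, 29.0- and 27.1-fold lower. Angptl2 (opposite an intron) was lower with a count ratio of 195, 95% interval 34.5 to 7729.6, adjusted p = 1.26e-06, and the calponin gene Cnn2 lower with a count ratio of 167, 95% interval 29.5 to 6644, adjusted p = 7.03e-06. Thbs2 was 93.1-fold lower, log2 fold change −6.54 ± 0.66 SE, adjusted p = 4.24e-06, and Tpm2, a tropomyosin, 78.3-fold lower, log2 fold change −6.29 ± 0.81 SE, adjusted p = 2.43e-05. Plau, the urokinase gene (chromosome 14, 20836660 to 20843385), was lower with a count ratio of 105, 95% interval 35.5 to 511, adjusted p = 4.63e-06.

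The oligodendrocyte precursor list was higher in PDGFB tumors and passed its test. In it 16 of 18 tested members were higher and 2 did not pass (16 and 0), with median 1.93, adjusted p = 5.01e-10, and adjusted p = 0.121 with an estimated correlation (alternatives 3.32e-13 to 0.121). The mesenchymal glioma list was lower in PDGFB tumors, with 15 of 19 members lower and 4 not past the threshold (0 and 16), and median −2.79, adjusted p = 1.36e-15, and adjusted p = 0.121 with an estimated correlation (alternatives 3.19e-22 to 0.121). Anxa1 (opposite an intron) was 59.5-fold lower, log2 fold change −5.89 ± 0.53 SE, adjusted p = 1.64e-06, and S100a6 35.4-fold lower, log2 fold change −5.15 ± 0.53 SE, adjusted p = 2.71e-06. Of the extracellular matrix list 14 of 16 were lower (0 and 14), with median −2.32, adjusted p = 1.16e-10, and adjusted p = 0.121 with an estimated correlation (alternatives 7.02e-12 to 0.121). Col5a2 was 16.4-fold lower, log2 fold change −4.03 ± 0.63 SE, adjusted p = 2.15e-04, and the basement membrane gene Nid1 (opposite Gm48682) 15.3-fold lower, log2 fold change −3.93 ± 0.39 SE, adjusted p = 2.06e-06. All 3 tested members of the fibroblast and meninges list were lower (0 and 3), with median −3.44, adjusted p = 0.0121, and adjusted p = 0.241 with an estimated correlation (alternatives 0.00145 to 0.241). Col1a2 was 15.1-fold lower, adjusted p = 8.77e-05, and Col1a1 10.9-fold lower, adjusted p = 0.00347. With the macrophage covariate Col1a2 had a log2 fold change of −0.068 (adjusted p = 0.980). Col1a1 was below the filter. Of the MAPK output list 8 of 17 were lower (0 and 9), with median −0.77, adjusted p = 0.00454, and adjusted p = 0.176 with an estimated correlation (alternatives 1.14e-04 to 0.176). Areg was 15.6-fold lower, log2 fold change −3.96 ± 0.68 SE, adjusted p = 4.36e-04, and Ereg (opposite Gm19610) 30.5-fold lower, log2 fold change −4.93 ± 0.57 SE, adjusted p = 1.40e-05. This call ended with the neuron covariate (median −0.67 against −0.77, adjusted p = 0.0610), the median changing little.

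Macrophage, monocyte-derived macrophage, MHC class I and ribosomal protein lists were lower in PDGFB tumors. Of the macrophage and microglia list 8 of 10 members were lower (0 and 9), with median −1.64, adjusted p = 2.87e-06, and adjusted p = 0.143 with an estimated correlation (alternatives 6.61e-08 to 0.814). Lyz2 was 9.25-fold lower, log2 fold change −3.21 ± 0.33 SE, adjusted p = 2.71e-06, and Laptm5, a lysosomal protein of leukocytes, 4.47-fold lower, log2 fold change −2.16 ± 0.40 SE, adjusted p = 5.94e-04. In the monocyte-derived macrophage list 6 of 8 were lower and 1 higher (1 and 7), with median −2.45, adjusted p = 1.38e-04, and adjusted p = 0.121 with an estimated correlation (alternatives 2.21e-05 to 0.121). Spp1 was 20.5-fold lower, log2 fold change −4.36 ± 0.45 SE, adjusted p = 2.40e-06, and the arginase gene Arg1 16.0-fold lower, log2 fold change −4.00 ± 0.69 SE, adjusted p = 3.17e-04. Of the MHC class I list 4 of 7 were lower (0 and 4), with median −2.01, adjusted p = 0.00206, and adjusted p = 0.241 with an estimated correlation (alternatives 9.93e-05 to 0.585). H2-K1 was 5.62-fold lower, log2 fold change −2.49 ± 0.47 SE, adjusted p = 6.83e-04. Erap1 (opposite Cast) was 4.84-fold lower, log2 fold change −2.27 ± 0.22 SE, adjusted p = 1.39e-06. Moved reads ended its call (log2 fold change −0.66, adjusted p = 0.0601) and left the list called at median −1.07. Of the ribosomal protein list 12 of 17 were lower (0 and 15), with median −0.89, adjusted p = 0.00196, and adjusted p = 0.491 with an estimated correlation (alternatives 2.08e-04 to 0.522). Rps2 (opposite Snhg9) was 2.24-fold lower, log2 fold change −1.16 ± 0.21 SE, adjusted p = 5.65e-04. Rpl19 was 2.41-fold lower, log2 fold change −1.27 ± 0.39 SE, adjusted p = 0.0183, with overlapping libraries, lost without RAS tumor 5 (adjusted p = 0.0763). Rpl19 and H2-K1 changed sign with the macrophage covariate (log2 fold change 1.69 and 0.12). With the macrophage covariate the MHC class I and ribosomal lists no longer passed (median −0.11 against −2.01, adjusted p = 0.585, and median 0.30 against −0.89, adjusted p = 0.522). The macrophage list's own adjusted p of 0.814 there follows by construction.

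Between the tumor groups, 15 lists did not pass. The cell cycle list had 5 of 15 higher and 1 lower (5 and 1), median 0.65, adjusted p = 0.0996; Cenpf was 3.77-fold higher, adjusted p = 0.00814, with overlapping libraries, and the list passed without PDGFB tumor 2 (adjusted p = 0.00420) and in genes with none on the opposite strand (0.0154, range over its alternatives 0.00420 to 0.556). Neural progenitor genes had 5 of 11 higher and 2 lower (5 and 2), median 0.48, adjusted p = 0.237, Dcx being the largest change. Mature oligodendrocyte genes had 2 of 7 higher and 0 lower (2 and 0), median 0.10, adjusted p = 0.416. Ugt8a, a myelin lipid enzyme, was 4.15-fold higher, adjusted p = 0.00877, with overlapping libraries. Neuron genes had 1 of 19 higher and 3 lower (1 and 3), median 0.42, adjusted p = 0.834, with a mean of −0.095 and a test that pointed down. Nefl (opposite Nefm) was 20.8-fold lower, log2 fold change −4.38 ± 0.37 SE, adjusted p = 4.01e-07. Astrocyte genes had 0 of 12 higher and 1 lower (0 and 1), median 0.31, adjusted p = 0.751. Slc1a2 (opposite Gm13872) had a log2 fold change of 0.59 and passed without RAS tumor 2 (1.60, adjusted p = 0.00237). Reactive astrocyte genes had 0 of 5 higher and 1 lower (0 and 1), median −0.72, adjusted p = 0.194. Vim was 2.49-fold lower, adjusted p = 3.07e-04. Homeostatic microglia genes had 0 of 4 higher and 2 lower (0 and 3), median −1.004, adjusted p = 0.130. Cx3cr1 (opposite Gm33858) was 2.07-fold lower, adjusted p = 0.00656, with overlapping libraries. MHC class II genes had 1 of 5 higher and 2 lower (2 and 3), median −1.72, adjusted p = 0.581. Cd74 was 10.6-fold lower, adjusted p = 6.77e-04. This list passed over genes with none opposite (median −2.77, adjusted p = 0.0292, 0.0292 to 0.998 over its alternatives), and its test turned upward without RAS tumor 2. Interferon response genes had 0 of 4 higher and 0 lower (0 and 0), median 0.31, adjusted p = 0.751. Irf7 (opposite Phrf1) had a log2 fold change of −0.71. The list passed with the macrophage covariate (median 2.04 against 0.31, adjusted p = 0.0106, 0.0106 to 0.975 over its alternatives). Classical glioma genes had 1 of 4 higher and 1 lower (1 and 1), median −0.66, adjusted p = 0.643, with a mean of 0.011. Cdh4, a cadherin, was 7.98-fold higher, adjusted p = 0.00132. Hypoxia and glycolysis genes had 1 of 11 higher and 4 lower (1 and 5), median −0.76, adjusted p = 0.156. Ndrg1 (opposite Gm17035) was 10.4-fold lower, adjusted p = 0.00122. The p53 targets had 1 of 9 higher and 3 lower (1 and 3), median −0.20, adjusted p = 0.562. Mdm2, the ubiquitin ligase that targets p53, was 3.90-fold lower, adjusted p = 0.00291. Immediate early genes had 0 of 5 higher and 0 lower (0 and 0), median −0.18, adjusted p = 0.854. Junb (opposite Prdx2) had a log2 fold change of −0.17. Cholesterol synthesis genes had 1 of 9 higher and 1 lower (1 and 1), median −0.13, adjusted p = 0.492. Fdft1 (opposite Ctsb) was 3.01-fold lower, adjusted p = 5.51e-06. Oxidative phosphorylation genes had 0 of 15 higher and 1 lower (0 and 0), median −0.29, adjusted p = 0.389. Atp5b, of the ATP synthase, had a log2 fold change of −0.30 (adjusted p = 0.181).

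Of the 24 lists tested, 9 were higher and 2 lower in PDGFB tumors than in normal brain, 9 and 2 in RAS tumors than in normal brain, and 1 and 8 in PDGFB than in RAS tumors. None of these calls held with the correlation between members estimated from the data (lowest adjusted p = 0.121), while all of them passed the rotation test fry, which asks only whether a list's genes moved one way.

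**Figure D2:**
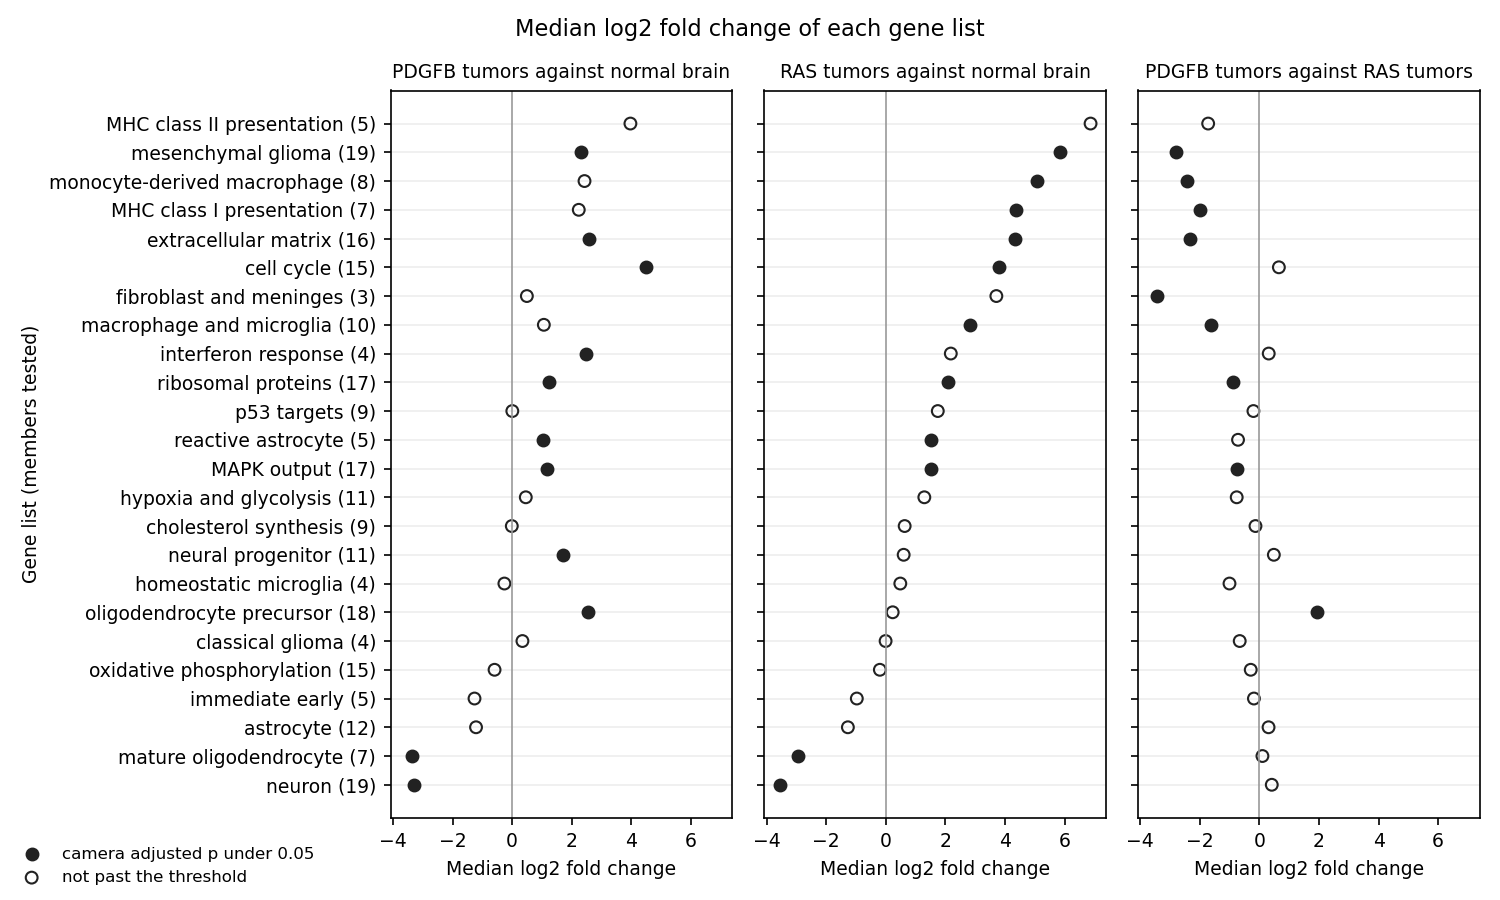
Median log2 fold change of each of the 24 gene lists in the 3 comparisons, 1 point per list with the members tested in parentheses; filled points passed camera's adjusted p under 0.05 and open points did not. The oligodendrocyte precursor list sits at 2.55 in PDGFB tumors against normal brain, at 0.23 in RAS tumors against normal brain and at 1.93 between the tumor groups.

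**Figure D3:**
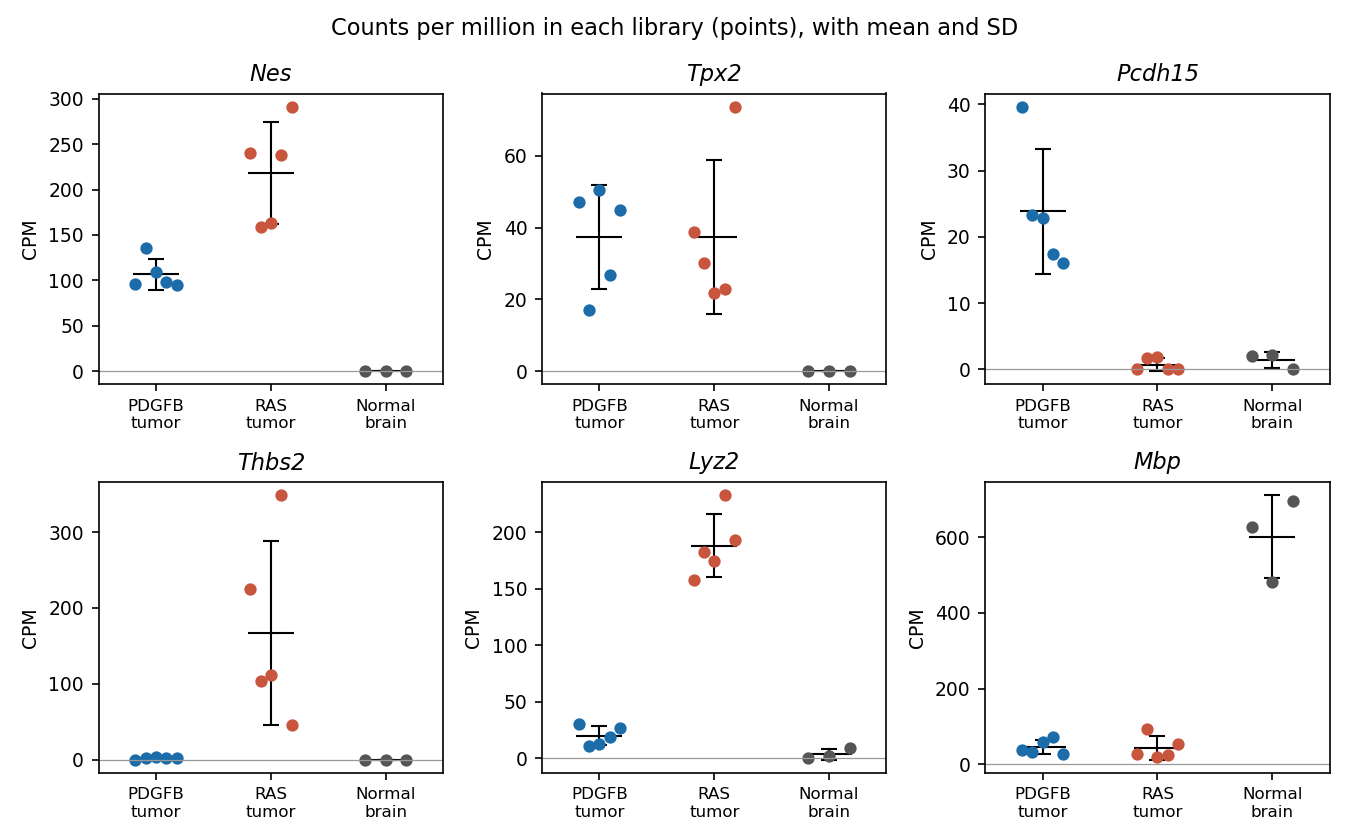
CPM of Nes, Tpx2, Pcdh15, Thbs2, Lyz2 and Mbp in each library (points), with the mean and SD of each group (horizontal lines, n = 5, 5 and 3). Thbs2 averages 167 CPM in RAS tumors and 1.60 in PDGFB tumors, and Mbp 601 in normal brain against 45.2 and 43.6 in PDGFB and RAS tumors.

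A further 8 lists had fewer than 3 members above the count filter, so their summed CPM were compared by two-sided exact permutation tests, whose smallest possible p is 0.0357 against normal brain and 0.00794 between tumors. None of these 24 tests passed after adjustment (lowest adjusted p = 0.0952). Values are means ± SD in PDGFB tumors (n = 5), RAS tumors (n = 5) and normal brain (n = 3), with exact p for PDGFB against normal, RAS against normal and PDGFB against RAS. Choroid plexus and ependyma genes, Ttr among them, had 8.49 ± 4.77, 15.7 ± 5.76 and 124 ± 50.8 CPM (exact p = 0.0357, 0.0357 and 0.0556). Cytokines and chemokines had 28.3 ± 12.2, 163 ± 58.7 and 19.5 ± 5.84 CPM (exact p = 0.321, 0.0357 and 0.00794). Endothelial genes had 68.2 ± 15.04, 119 ± 18.4 and 48.7 ± 6.83 CPM (exact p = 0.107, 0.0357 and 0.00794), and pericyte and smooth muscle genes 87.0 ± 14.97, 147 ± 59.4 and 80.2 ± 1.998 CPM (exact p = 0.464, 0.143 and 0.0556), of which Tagln (opposite Gm48529) held 64.5, 75.7 and 26.8. T and NK cell genes had 298 ± 52.8, 452 ± 206 and 222 ± 20.3 CPM (exact p = 0.0357, 0.0357 and 0.0556). Nearly all of it was Foxp3 (opposite Ccdc22), at 296, 448 and 215 CPM, so the sum says little of T cells. Neutrophil genes had 11.6 ± 7.40, 40.9 ± 45.3 and 2.65 ± 1.10 CPM (exact p = 0.0357, 0.143 and 0.0952). B cell genes had 1.87 ± 1.71, 7.59 ± 8.10 and 8.35 ± 5.36 CPM (exact p = 0.143, 0.929 and 0.246), and red blood cell genes 14.0 ± 5.71, 19.3 ± 10.96 and 25.8 ± 15.1 CPM (exact p = 0.214, 0.50 and 0.365).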

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

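The tests of strand, of RAS tumor 2 and of tumor cell content were chosen after the results were seen, and those of scaling, of a gene on the opposite strand and of regrouped samples before.

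Genes held few reads, and the highest of them lay opposite abundant genes. If libraries that mark strand were counted on the strand opposite to each gene, genes opposite an exon would hold several times their share of exon length, and they held 3.12 times that share. Libraries that do not mark strand are excluded, as mt-Nd6 held at least 1.80 times the reads of the other 12 mitochondrial messengers. Counted reads per kb of exon differed 14.6-fold between genes with and without an exon opposite, leaving uncounted genomic or intronic reads open. Counting on the opposite strand is therefore a candidate explanation, which the kit leaves open and the sequence reads could settle. No biological explanation was tested.

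RAS tumor 2 lay closer to normal brain than the other RAS tumors. On a scale from the other RAS tumors (0) to the PDGFB tumors (1) it stood at 0.505 and RAS tumor 3 at 0.329, and a swap with a PDGFB tumor was first to be excluded under 0.5, which RAS tumor 2 missed; the exclusion rests on a criterion added once that was known, that a swap needs a PDGFB tumor out of place, and the lowest stood at 0.944. Normal tissue in the piece should raise neuron, myelin and astrocyte genes to the same share of their normal level, and the medians were 23.7% ± 3.52, 22.2% ± 10.1 and 79.1% ± 27.0 (bootstrap SE), with neuron minus myelin 1.56 ± 10.7 points, within the limit of 2 SE set for exclusion, but astrocyte minus neuron 55.4 ± 27.2, just over 2 SE and against equal shares. Shares first taken from summed CPM, −105% ± 141 for neurons and 13.9% ± 4.79 for myelin, were replaced by medians once seen and decide no more. Normal tissue and another tumor biology cannot be told apart, and sex, not modelled, may add. Of RAS tumors only this one had Y-linked Ddx3y reads (11, with 1 of Xist and 0 of Tsix). So did PDGFB tumors 2 and 4 (6 and 3) and normal brain 1 (5).

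Oligodendrocyte precursor genes were lower in RAS than in PDGFB tumors. The difference exceeded that of the cell cycle and neural progenitor genes by 1.30 ± 0.42 (log2, SE), but normal brain held 39.7% and 55.3% of their level in RAS tumors, over a limit of 10% that was added once the test had first been read as an exclusion, so it decides nothing. The list passed under library totals and median-of-ratios factors (camera, higher adjusted p = 1.09e-09). Camera sets a list against all other genes, so a shift common to all genes largely cancels and this test cannot exclude scaling. The median gene itself shifted by 0.14 and 0.0057 under these scalings, against a list median of 1.93. A gene on the other strand is excluded, since the 9 members without one had a median log2 difference of 2.34. With the macrophage covariate the median was 1.42 (adjusted p = 0.0309, 3.32e-13 to 0.121 over the alternatives). A smaller share of tumor cells in RAS tumors and an effect of the oncogene cannot be told apart here, since neither of those lists could be shown to be confined to tumor cells.

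Regrouping the samples tested whether chance gives as many calls, in fits of the 2 groups alone. For PDGFB tumors against normal brain the real groups gave 3961 genes and other splits 0 (1 of 56 as large). RAS tumors against normal brain gave 3813 against at most 480 (1 of 56), where RAS tumors 2 and 3 joined the normal brains. Between tumors it was 1829 against 0 (1 of 100 drawn from 126). Mixed splits count the group difference as spread. Chance is bounded only at 1 of 56 or 1 of 100, if libraries are separate animals.

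In 38 genes the tumor groups differed from normal brain in opposite directions, with PDGFB below RAS tumors in 23, and the difference between tumors passed in all of them. Of the named genes, Dmrt1i (opposite Baiap2l1) averaged 0, 27.4 and 3.23 CPM in PDGFB tumors, RAS tumors and normal brain, with a fitted log2 difference between tumors of −7.005 that is no bound. Fdft1 (opposite Ctsb, a lysosomal protease) had log2 fold changes of −0.64 and 0.95 against normal brain and differed by −1.59 between tumors (adjusted p = 5.51e-06). Fam69c (opposite D030046N08Rik) had 2.28 and −1.53, and 3.80 between tumors (adjusted p = 1.18e-05).

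A library stood apart from the others of its tumor group, by Dixon's test at the 95% level, in 64 of 312 tests of depth, gene lists and named genes, where chance alone gives about 1 in 20, or 15.6. The tests share libraries and genes, and a value against others at 0 can rest on a single read. Values are CPM, summed over a list where a list is named, with the range of the other 4 libraries. RAS tumor 2 had 19, mostly neuron, myelin and astrocyte genes: astrocyte list 544 (others 160 to 258), Aldoc 60.2 (others 3.37 to 19.3), Arc 13.4 (others 0 to 3.37), Camk2a 92.0 (others 1.68 to 9.09), Epyc 1.67 (others 0), Hpca 8.37 (others 0 to 1.75), Ifit2 48.5 (others 8.41 to 19.3), Krt12 6.69 (others 0 to 1.75), Mag 13.4 (others 0 to 1.75), Mobp 63.6 (others 0 to 12.3), Myocos 6.69 (others 0 to 1.75), Neurod2 5.02 (others 0), Rph3a 11.7 (others 0 to 1.75), Scn9a 6.69 (others 0 to 1.75), Slc1a2 112 (others 15.8 to 22.8), Snap25 70.3 (others 0 to 19.3), Strc 1.67 (others 0), Tmem130 5.02 (others 0) and Vmn2r57 1.67 (others 0). RAS tumor 5 had 13, of fibroblasts, antigen presentation and others, with the T and NK cell list nearly all Foxp3 (opposite Ccdc22): neutrophil list 119 (others 1.82 to 31.5), T and NK cell list 809 (others 276 to 404), fibroblast and meninges list 462 (others 98.2 to 159.9), Cd74 112 (others 10.5 to 36.8), Col1a2 179 (others 30.9 to 70.3), Col6a1 146 (others 28.4 to 53.9), H2-D1 295 (others 89.2 to 109), H2-K1 267 (others 52.7 to 107), Il27 242 (others 50.9 to 80.8), Irf7 64.9 (others 10.1 to 25.1), Plau 239 (others 40.2 to 92.8), Rpl19 288 (others 52.2 to 96.3) and Tpm2 323 (others 38.2 to 103).

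In RAS tumor 1 there were Myh7 1.68 (others 0) and Scn3b 1.68 (others 0). In RAS tumor 3 there were Gpnmb 5.45 (others 23.6 to 30.1), Napsa 1.82 (others 0) and Pnlip 16.4 (others 0 to 3.37). PDGFB tumor 1 had H2-DMa 294 (others 213 to 226), Trp53 1.52 (others 3.11 to 3.25, or 1 read against 2 in each) and reads counted for genes 637560 (others 604700 to 613100). PDGFB tumor 2 had classical glioma list 139.8 (others 94.5 to 104), Angptl2 1.55 (others 0), Cacng3 1.55 (others 0), Cdsn 163 (others 61.8 to 88.7), Cnn2 1.55 (others 0), Myh7 1.55 (others 0), Pdgfa 74.5 (others 24.4 to 36.4) and Ttr 3.11 (others 0). PDGFB tumor 3 had mature oligodendrocyte list 934 (others 833 to 857), Myocos 1.63 (others 0), Scn9a 6.51 (others 1.52 to 1.60) and Serpina3n 86.2 (others 59.0 to 64.0). PDGFB tumor 4 had astrocyte list 410.2 (others 239 to 270), Col5a2 7.92 (others 0 to 1.63), Epyc 19.0 (others 0 to 3.25), Krt12 12.7 (others 0 to 1.55) and Slc1a2 119 (others 29.0 to 53.7). PDGFB tumor 5 had MHC class I presentation list 464 (others 226 to 279), interferon response list 204 (others 129 to 148), Col1a2 14.4 (others 1.55 to 3.25), H2-D1 73.8 (others 14.2 to 31.1), H2-K1 49.8 (others 12.2 to 18.6) and Phlda1 38.5 (others 56.4 to 59.0).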

How the results depend on the processing

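The genes with none opposite, the moved reads and the attention to RAS tumor 2 were chosen after seeing the data. Of the counts of genes, lists and shared genes, 284 results under alternatives stayed within 1.5 times the value reported and 30 did not. Of 147 called results for named genes, 114 kept direction and threshold in each alternative that tested them, and 135 did apart from the macrophage covariate. Only 75 were tested in all alternatives, since some alternatives leave out genes. Of 47 calls between tumors the macrophage covariate tested 30, of which 8 stayed, and 14 of the 22 lost kept at least 0.5 of their log2 fold change, a limit set after the values were seen. So did 30 of the 33 losses in other alternatives. Over all alternatives named genes gave 3425 unchanged, 53 weaker, 1 stronger and 21 reversed results, and lists 1308, 40, 34 and 22. Leaving out 1 library gave 1383 to 1841 higher and 1513 to 1895 lower genes in PDGFB tumors against normal brain, 1919 to 2311 and 1945 to 2216 in RAS tumors against normal brain, 919 to 1541 and 1088 to 1502 between tumors, and 968 to 1308 and 1269 to 1554 shared. Higher and lower lists were 8 to 10 and 2 to 3, 9 and 2, and 1 to 2 (2 without PDGFB tumor 2) and 7 to 8.

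Genes with none opposite gave 618 higher and 585 lower genes in PDGFB tumors against normal brain, 824 and 728 in RAS tumors against normal brain and 408 and 435 between tumors, and 424 and 494 shared, as fewer genes were tested (2866). Under an adjusted p of 0.01, which by construction calls fewer, 988 genes were higher in PDGFB tumors against normal brain, and 626 higher and 839 lower between tumors. Between tumors the macrophage covariate left 4 higher and 57 lower genes, and 2 higher and 4 lower lists. Equal numbers in the titles did not pair the tumor groups: deviations from the group means correlated across genes at −0.128 to 0.139, and 1 of 5 PDGFB tumors correlated best with the RAS tumor of its own number. With that number as a replicate block 815 genes were higher and 890 lower, and the calls of the MAPK output list (median −0.70, adjusted p = 0.0725, 1.14e-04 to 0.176 over its alternatives) and of Rpl19 (log2 fold change −1.01, adjusted p = 0.0527, 6.93e-04 to 0.460) missed the threshold, and no other call of a list or named gene tested there did. Normal brains are labelled otherwise, and no fit with a block was run against them. An estimated correlation left 0 lists in each direction and comparison. Fry gave 5 lower lists in PDGFB tumors against normal brain, 15 higher and 5 lower in RAS tumors against normal brain, and 3 and 13 between tumors, as it does not compare a list with other genes. Higher lists between tumors numbered 2 in genes with none opposite and 2 with moved reads. Apart from the reasons stated, the cause was not tested.

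Direction reversed in the settings given in parentheses, and the cause was not tested. For a gene this is the sign of its log2 fold change. For a list it is the direction of its test, which weighs all members, so the median printed here did not always change sign. In PDGFB tumors against normal brain, reversed results stood at homeostatic microglia 0.31 (RAS tumor 5 out), homeostatic microglia 0.42, classical glioma 1.51, H2-DMa 0.043 (normal brain 1 out), homeostatic microglia 0.32, classical glioma 1.03 (normal brain 3 out), classical glioma 0.025, Parpbp 3.77, H2-DMa 0.34 (moved reads), classical glioma 0.44 (RAS tumor 2 out), classical glioma 1.38 (normal brain 2 out), Cnp 0.047, H2-DMa 0.11 (library totals), Col1a2 −0.44 (PDGFB tumor 5 out), H2-DMa 0.0062 (no filter), H2-DMa 0.011 (the looser filter) and H2-DMa 0.0076 (the 2 groups alone). In RAS tumors against normal brain, reversed results stood at Pdgfa 0.052, Ndufs1 2.80, Parpbp 2.95 (moved reads), Pdgfa 0.089 (RAS tumor 2 out), Pdgfa 0.099 (RAS tumor 5 out) and Pdgfa 0.15 (normal brain 3 out). Between tumors, reversed results stood at astrocyte 0.12, neuron 0.57, immediate early −0.16 (genes with none opposite), neural progenitor −0.12, neuron 2.62, oxidative phosphorylation 0.14, ribosomal proteins 0.30, Cnp −0.13, Rpl19 1.69, Irf7 2.97, Junb 0.39, H2-K1 0.12 (the macrophage covariate), neuron 0.71, interferon response −0.27, cholesterol synthesis 0.42, Napsa −0.47 (moved reads), neuron 0.57 (PDGFB tumor 1 out) and neuron 1.93, immediate early −0.067, MHC class II presentation −0.44 (RAS tumor 2 out). Over all libraries left out, log2 fold changes of these ranged in PDGFB tumors against normal brain as homeostatic microglia −0.30 to 0.42, classical glioma 0.29 to 1.51, Col1a2 −0.44 to 1.21, H2-DMa −0.21 to 0.043, in RAS tumors against normal brain as Pdgfa −0.18 to 0.15, and between tumors as neuron 0.20 to 1.93, immediate early −0.37 to −0.023, MHC class II presentation −2.85 to −0.063.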

Other observations

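The tests in this part were chosen after the results were seen. Reads were given to the gene on the opposite strand, and values here are those of the gene after this move. Genes with at least 50 CPM in the higher group and at least 50% of their reads moved were ranked by fold. In PDGFB tumors against normal brain the mitotic genes Ckap2l, Ccna2, Prc1 and Kif20a were 95.9-fold higher, 66.4-fold higher, 63.3-fold higher and 40.5-fold higher (adjusted p at most 1.68e-07, n = 5 and 3, edgeR). Ccnd1 (chromosome 7, 144929931 to 144939925), the D-type cyclin, averaged 29427 ± 5720.2 CPM in PDGFB tumors, 31632 ± 8563 in RAS tumors and 614 ± 81.8 in normal brain. The matrix gene Tnc was 90.7-fold higher in PDGFB and 382-fold higher in RAS tumors, and Hmga2 averaged 161 and 1232 CPM in these, against 0 in normal brain. Pmch, of hypothalamic neurons, averaged 789 CPM in normal brain and was 258-fold lower and 193-fold lower in PDGFB and RAS tumors.

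Between tumors, moved reads put Gpr17 and Hes5, genes of oligodendrocyte precursors and of Notch signaling, 7.24-fold higher and 12.3-fold higher in PDGFB tumors (adjusted p = 2.45e-04 and 4.00e-05), and the adhesion gene Dscam 12.4-fold higher (adjusted p = 9.24e-06). Fosl1, a transcription factor induced by Ras signaling (chromosome 19, 5447547 to 5455946), was 25.4-fold lower (adjusted p = 1.84e-08), at 84.3 ± 19.1 CPM against 2143 ± 816 in RAS tumors and 11.2 ± 2.17 in normal brain. Tfap2a averaged 6.34 and 387 CPM in PDGFB and RAS tumors and was 58.8-fold lower. The neurofilament gene Nefl averaged 299 CPM in PDGFB tumors, 6074 in RAS tumors and 4976 in normal brain.

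With moved reads, lists that had not passed did so: MHC class I in PDGFB tumors against normal brain (adjusted p = 0.0144, 0.00903 to 0.433 over its alternatives), monocyte-derived macrophages there (0.0188, 0.00612 to 0.389), interferon response in RAS tumors against normal brain (0.0117, 0.00145 to 0.409) and the cell cycle between tumors (0.00962, 0.00420 to 0.556). In 1965 pairs of genes with overlapping exons, fold changes of the members correlated across pairs at r = 0.581, 0.636 and 0.621 in the 3 comparisons, against at most 0.0681 in 1000 shuffles; pairs are not independent replicates. Tsix, opposite Xist, had more reads than Xist in 8 of the 9 libraries with 10 reads of either.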
